A study of Homo sapiens with 4 samples.

How the data were processed

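Poly-A-selected RNA from U251 cells was made into strand-specific libraries and sequenced as paired-end reads on an Illumina NextSeq500, per the labels' protocols. For the processing, the sample records used here list STAR, featureCounts and the genome build hg19, without versions. These records may not hold all of the submitters' processing notes. The authors deposited 1 table for the whole series, with 4 columns of whole numbers per gene that have the form of read counts.

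Each sample was assigned to a group from its title, which gave 4 groups of 1 sample. The table's columns were then compared by name with the text of the sample and series records used here. None of the 4 column names occurs there, so 4 columns of sample values were not used, and 0 columns were matched to a sample. These records may be less than the full public record, so a key to the columns may exist elsewhere. Column order and expression values were not used as a substitute. The ratios, gene list summaries and correlations planned before the data were examined were not computed, and no other settings were tried for them.

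Only the gene identifier column was analysed, with Python 3.11.15 and pandas 2.3.3. Identifiers were compared without their version numbers with the gene annotation of GENCODE release 29, which gave the gene types. That release is built on GRCh38 and not on hg19, so no coordinates are given. A table of current identifiers and symbols held 19460 of the 20361 identifiers and lacked 901.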

Results

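Messenger RNA of the human glioma cell line U251 was profiled in 4 groups of cells, with 1 library per group. In 2 of the groups endogenous GCN5 had been depleted. GCN5, encoded by KAT2A, is a lysine acetyltransferase of the SAGA and ATAC coactivator complexes. These cells had then been given a Flag-tagged GCN5, either wild type or carrying the Y645A substitution. In the other 2 groups endogenous DLST had been depleted. DLST is the dihydrolipoamide succinyltransferase subunit of the alpha-ketoglutarate dehydrogenase complex, which makes succinyl-CoA in the tricarboxylic acid cycle. These cells had then been given a V5-tagged DLST, either wild type or carrying both the R224A and K226E substitutions.

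The design implies a comparison of each mutant with its own wild type, and a comparison of the transcripts affected in the GCN5 mutant with those affected in the DLST mutant. No such comparison is made here. The deposited table has 4 columns of values, and the names of these columns match none of the labels of the 4 samples. With the records used here, assigning them would have rested on the order of the columns or on the expression values themselves. The direction of every mutant to wild-type difference would have depended on that assignment. The expression values were therefore not analysed here, and no level, fold or depth is given for any library.

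The gene identifiers of the table carry no sample values and were examined. The table lists 20361 genes by versioned Ensembl identifier, each identifier once. Of these, 19525 were found in GENCODE release 29 when version numbers were ignored, and 836 were not. Protein-coding genes made up 19023 of the genes found. The other 502 were of other types in that release, chiefly 217 long intergenic RNAs and 140 antisense RNAs. These types are those of release 29 only. The types of the same genes in the annotation used for counting were not examined and may differ. The 13 protein-coding genes of the mitochondrial genome were included. Both genes that the design targets were listed, KAT2A as ENSG00000108773.6 and DLST as ENSG00000119689.10.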

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

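No comparison between samples was made because no column of values was matched to a sample by its name. For the same reason no other scaling factors, filters on low counts, prior counts or fold thresholds were tried. The only result open to another setting was the match of gene identifiers to an annotation, and its alternatives were chosen after seeing the data. With version numbers ignored, 19525 of the 20361 identifiers were found in GENCODE release 29, and 2704 were found when the version number also had to match. The lower count concerns version numbers and does not mean that fewer of the genes were in that release. A separate table of current identifiers and symbols, with version numbers ignored, held 19460 of the 20361 identifiers. How many of these were also among the 19525 was not computed.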
